A study of Arabidopsis thaliana with 18 samples.

How the data were processed

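The series measured messenger RNA in whole rosettes of 3-week-old Arabidopsis thaliana plants of 3 genotypes. Col-0 is the standard laboratory accession, Cvi-0 is an accession from the Cape Verde islands that is sensitive to ozone, and Col-S is a near-isogenic line that carries the ozone sensitivity of Cvi-0 in a Col-0 background. Each genotype was sampled under control conditions and after 2 h at 350 ppb ozone. A library came from a pool of 10 to 15 rosettes, and each of the 6 groups had 3 biological replicates, giving 18 libraries. Per the labels, libraries were made with the TruSeq RNA kit, version 2. The submitters' processing notes name FastQC, TopHat2, SAMtools, HTSeq and the genome build TAIR10. Their versions, the strandedness of counting, the counting mode and the handling of reads that map to several places are not given in the sources used here. The deposited files hold raw whole-number counts per gene and library with no normalization. They list 32678 genes with their coordinates, and 31912 of these codes had an entry in the table of gene names. The 279 genes of the organelles have a count of 0 in every library, so an alternative without organelle genes could not be run.

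Total counts per library ranged from 14905841 to 26171613, so that a floor of 3 counts corresponded to 0.115 to 0.201 CPM (counts scaled to a common library total). Intervals and floors cover counting error only. Where a group had no count at all for a gene, a fold is given as a lower bound against 3 counts over the group, and where it had 1 to 3 counts, the ratio of CPM is given with its exact 95% interval. CPM values are means of TMM-scaled values over 3 libraries with the SD. Log2 fold changes come with the SE of the fit.

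Genes were tested with edgeR 4.0.16 in R 4.3.3, with the packages data.table (version 1.17.8) and jsonlite (version 2.0.0) to read the files. The filter for low counts kept 20622 genes. TMM factors scaled the libraries, and 1 quasi-likelihood fit of all 18 libraries with a mean per group gave 12 residual degrees of freedom. The comparisons were ozone against control in each genotype, the difference of these responses between each pair of genotypes (an interaction contrast), and the controls of each pair of genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes of that comparison. The number that also changed at least 2-fold is given beside each count. All p-values of genes are edgeR adjusted p-values unless stated otherwise.

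The tests, the gene lists, the rule for the genes named and the processing alternatives were fixed before the data were examined. The rule took the 5 highest and 5 lowest genes by log2 fold change in each comparison, among called genes with an average log2 CPM of at least 1 and, for the ozone responses, no overlap between the 3 ozone and the 3 control values. It also took up to 4 called members of each list with the smallest p, or the member with the smallest p where none was called, and MPK12 in every comparison. Genes named outside it are said to be so. Genes that overlap another annotated gene are pointed out, because their reads may be shared.

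The 22 gene lists covered ethylene, jasmonate, salicylic acid and abscisic acid, antioxidant enzymes, regulators that respond to reactive oxygen, glutathione transferases, WRKY factors, cysteine-rich receptor-like kinases, calcium, touch and MAP kinase signalling, tryptophan and camalexin synthesis, phenylpropanoid and flavonoid synthesis, aliphatic glucosinolates, heat shock, photosynthesis, auxin and cell expansion, senescence and cell death, the clock, guard cells, reference genes, and markers of roots and of flowers as organs a rosette sample could hold. Of 406 entries, 392 were matched by symbol or synonym, 6 were spelled otherwise and 8 had no symbol. The gene PAT1 of the tryptophan list was kept under the code AT5G17990, which the name table calls TRP1. Each list was tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, which sets a list against the other genes. Its p-values were adjusted over the 189 tests of lists and comparisons. The root list had 1 tested gene and no list test. No list call held when the correlation was estimated from the data. The test fry, whose p asks whether the genes of a list move on balance one way, was an alternative. For each list the number of calls adjusted over the list alone is given beside that over all genes.

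The size of the ozone response was compared between genotypes by total least squares through the origin over 16238 genes called for the average ozone effect, with a jackknife SE over libraries. Called genes that differed at least 2-fold between Cvi-0 and Col-0 controls were used to look for stretches of Cvi-0 origin in Col-S. A gene was called Cvi-like where its mean in Col-S controls lay nearer to Cvi-0 than to Col-0 on the log2 scale, and each bin of 1 Mb with at least 5 such genes was compared with the rest of the genome by Fisher's exact test.

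Replicate numbers were checked for pairing by correlating the deviations from group means of same-numbered libraries. All pairs exceeded 0.1 in the Col-S ozone comparison, with values from 0.128 to 0.279, and in the controls of Cvi-0 and Col-0, from 0.104 to 0.290, of Col-S and Col-0, from 0.306 to 0.426, and of Col-S and Cvi-0, from 0.175 to 0.360, but not in the others. Alternatives were DESeq2 1.42.0 size factors, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, only the groups compared in the fit, the DESeq2 Wald test, an estimated correlation and fry for lists, all tested genes for the response size, and a larger change, wider bins or more genes per bin for the stretches. Thinning all libraries to the smallest total was added after the data had been seen. The tests were also run on simulated data with known changes: of 100 genes given a 4-fold change in a comparison, between 86 and 100 were recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.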

Results

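The data are messenger RNA counts from whole rosettes of Col-0, the ozone-sensitive Cvi-0, and Col-S, a sensitive line in a Col-0 background. Each genotype gave 3 control libraries and 3 after 2 h at 350 ppb ozone. Total counts ranged from 16618338 to 23691876 in Col-0 controls, from 19011751 to 25789925 in Col-0 ozone, from 15392332 to 26171613 in Cvi-0 controls, from 14905841 to 18339372 in Cvi-0 ozone, from 18344539 to 19961690 in Col-S controls and from 15887138 to 21386870 in Col-S ozone libraries. The first principal component held 67.1% of the variance and separated control from ozone libraries, and the second held 20.8% and separated Cvi-0 from the other genotypes. On the first component Col-0 control replicate 2 scored -92.1, and the other Col-0 controls scored -121.3 and -115.7. Col-0 ozone replicate 2 scored 54.5 against 79.9 and 89.8, and Col-S ozone replicate 2 scored 108.1 against 124.7 and 138.2. The 10 most abundant genes took 10.3% ± 0.353 of the counts in Col-0 controls and 6.75% ± 0.774 after ozone (SD, n = 3), with 9.77% ± 0.329 and 4.90% ± 0.113 in Cvi-0 and 9.76% ± 0.430 and 5.35% ± 0.232 in Col-S.

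**Figure D1:**
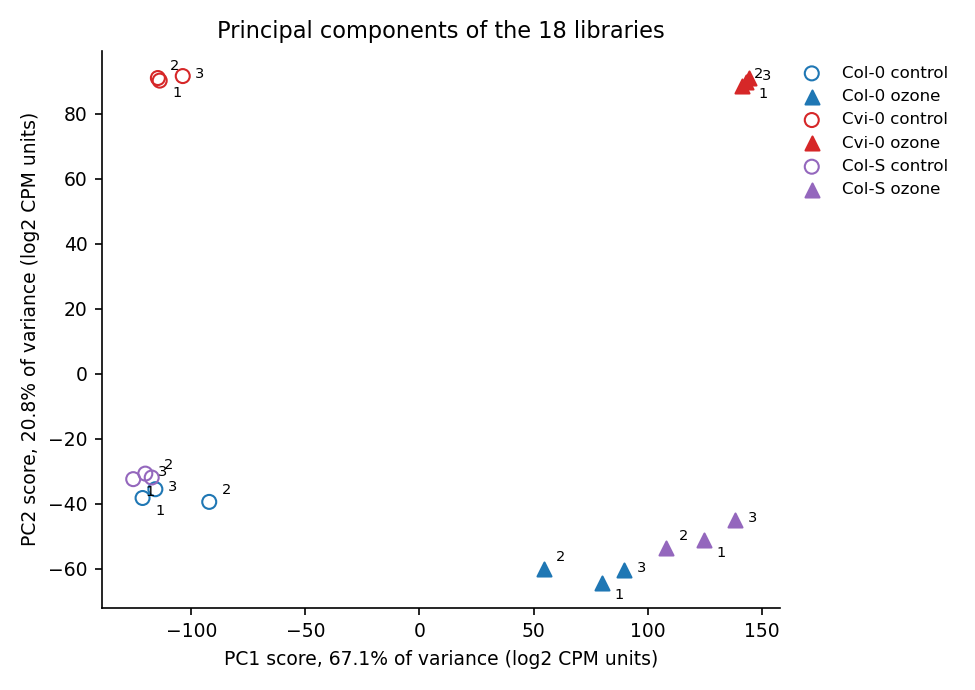
Principal components of log2 CPM, with the first component (67.1% of the variance) on the x axis and the second (20.8%) on the y axis, 1 point per library. Circles are controls, triangles are ozone libraries, colours are genotypes and numbers are replicates; the Cvi-0 libraries lie between 88.5 and 91.6 on the second component and all others between -64.2 and -30.7.

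The first comparison asked what 2 h of ozone did to the transcripts of Col-0 rosettes. Most tested genes of the ethylene, jasmonate, WRKY, calcium and MAP kinase, camalexin and heat shock lists rose. Most of those of the auxin and cell expansion, glucosinolate and photosynthesis lists fell. ACO4 (AT1G05010), an enzyme of the last step of ethylene synthesis, went from 146 ± 18.5 to 1982 ± 369.8 CPM (SD, n = 3), and CYP71A12 (AT2G30750), a cytochrome P450 of camalexin synthesis, from 0.694 ± 0.533 to 394 ± 95.9 CPM. IAA3 (AT1G04240), a repressor of auxin signalling, went down from 32.5 ± 8.04 to 4.24 ± 1.98 CPM. Of 20622 tested genes, edgeR called 6145 higher and 5679 lower, and 3501 and 1760 of these changed at least 2-fold.

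The steepest rises in Col-0 were those of the acyltransferase gene AT5G61160 (chromosome 5, 24608724 to 24610304), with a log2 fold change of 11.30 (SE 0.49, adjusted p = 1.2e-11), and of AT1G59950, CYP82C3 (AT4G31950) and AT3G44830, with 1 to 2 counts over the control group. Ratios to control were 2324 (95% interval 417 to 91816) for AT1G59950, 1490 (412 to 12307) for CYP82C3, a cytochrome P450, and 1455 (261 to 57513) for AT3G44830. PROPEP2 (AT5G64890), a precursor of a danger peptide, had no count in controls and was at least 86.6-fold higher. The steepest falls included AT1G29450, a small auxin-up RNA gene, at -4.52 (SE 0.40, adjusted p = 3.7e-08), the expansin EXPA8 (AT2G40610) at -4.40, SAUR27 (AT3G03840) at -4.25, and BAS1 (AT2G26710), which inactivates brassinosteroids, at -4.16.

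By list, the camera test called 14 of the lists in Col-0. Of 19 ethylene genes, 17 rose, 0 fell and 2 were not called (17 and 0 adjusted over the list alone). Their median log2 fold change was 3.76 (adjusted p = 5.5e-07, 0.187 with an estimated correlation). The factor ORA59 (AT1G06160) rose by 6.40 (SE 0.33, adjusted p = 6.3e-11) and ACS6 (AT4G11280), which makes the ethylene precursor, by 3.90. Of 21 jasmonate genes, 16 rose, 1 fell and 4 were not called (16 and 1 adjusted over the list alone). The median was 2.24 (adjusted p = 7.5e-06, 0.449 with an estimated correlation). JAZ1 (AT1G19180), a repressor that jasmonate removes, was at 5.50 and LOX4 (AT1G72520) at 5.23. Of 19 salicylic acid genes, 16 rose, 0 fell and 3 were not called (17 and 0 adjusted over the list alone). This list had a median of 2.18 (adjusted p = 2.6e-05, 0.461 with an estimated correlation). ICS1 (AT1G74710), the main enzyme of salicylic acid synthesis, went from 29.3 ± 15.0 to 263 ± 36.2 CPM, a change of 3.16 (SE 0.27, adjusted p = 3.0e-08). SAG101 (AT5G14930), a partner in defence signalling, changed by 2.99. Of 20 WRKY factors, 20 rose, 0 fell and 0 were not called (20 and 0 adjusted over the list alone). The median was 4.62 (adjusted p = 1.6e-10, 0.187 with an estimated correlation). WRKY45 (AT3G01970) rose by 5.05 and WRKY15 (AT2G23320) by 4.25. WRKY40, which AT1G80850 overlaps, had 6.70, and WRKY33, which AT2G38480 overlaps, 5.28.

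Of 13 calcium, touch and MAP kinase genes, 13 rose, 0 fell and 0 were not called (13 and 0 adjusted over the list alone). The median was 2.72 (adjusted p = 5.8e-08, 0.187 with an estimated correlation). MKK4 (AT1G51660), a MAP kinase kinase, rose by 3.23 (SE 0.14, adjusted p = 1.1e-11) and the calmodulin-like TCH3 (AT2G41100) by 4.76. Of 15 regulators that respond to reactive oxygen, 13 rose, 0 fell and 2 were not called (13 and 0 adjusted over the list alone). The median was 3.55 (adjusted p = 2.8e-07, 0.187 with an estimated correlation). RBOHD (AT5G47910), an NADPH oxidase, was at 2.77 and the zinc finger gene ZAT6 (AT5G04340) at 5.34. Of 18 cysteine-rich receptor-like kinases, 16 rose, 1 fell and 1 was not called (16 and 1 adjusted over the list alone). The median was 2.65 (adjusted p = 1.3e-06, 0.189 with an estimated correlation). CRK11 (AT4G23190) was at 5.74. Of 16 tryptophan and camalexin genes, 14 rose, 0 fell and 2 were not called (14 and 1 adjusted over the list alone). The median was 3.36 (adjusted p = 3.5e-08, 0.187 with an estimated correlation). ASA1 (AT5G05730), at the entry to tryptophan, was at 3.43 and CYP71A12 (AT2G30750) at 9.05. Of 17 heat shock genes, 14 rose, 0 fell and 3 were not called (14 and 0 adjusted over the list alone). The median was 2.62 (adjusted p = 1.6e-05, 0.303 with an estimated correlation). HSFA2 (AT2G26150), a heat shock factor, was at 5.67 (SE 0.20, adjusted p = 2.7e-12) and HSP90.1 (AT5G52640) at 6.10. Of 31 glutathione transferases, 22 rose, 5 fell and 4 were not called (22 and 5 adjusted over the list alone). The median was 2.63 (adjusted p = 5.3e-05, 0.303 with an estimated correlation). GSTU3 (AT2G29470) was at 7.56. The number of transferases that fell was 3 without Col-0 control replicate 3, Col-0 ozone replicate 1 or Col-0 ozone replicate 3. Of 12 senescence and cell death genes, 8 rose, 1 fell and 3 were not called (9 and 1 adjusted over the list alone). The median was 1.55 (adjusted p = 0.0138, 0.272 with an estimated correlation). The metacaspase MC8 (AT1G16420) was at 5.54 and the transporter SAG29 (AT5G13170) at -2.60.

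The lists that fell were those of auxin, glucosinolates and photosynthesis. Of 21 auxin and cell expansion genes, 1 rose, 16 fell and 4 were not called (1 and 17 adjusted over the list alone). The median was -1.59 (adjusted p = 4.1e-06, 0.272 with an estimated correlation). PIN3 (AT1G70940), an auxin carrier, changed by -2.12 (SE 0.21, adjusted p = 1.6e-07). Of 18 aliphatic glucosinolate genes, 0 rose, 14 fell and 4 were not called (0 and 14 adjusted over the list alone). The median was -0.94 (adjusted p = 4.8e-04, 0.461 with an estimated correlation). The regulator MYB28 (AT5G61420) changed by -1.40. Of 36 photosynthesis genes, 0 rose, 32 fell and 4 were not called (0 and 33 adjusted over the list alone). The median was -0.60 (adjusted p = 4.2e-06, 0.616 with an estimated correlation). RCA (AT2G39730), which activates Rubisco, changed by -0.81.

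camera did not call the remaining lists in Col-0. fry called the antioxidant (adjusted p = 6.4e-04), guard cell (0.0016) and reference gene lists (1.2e-05), the last 2 in all 3 genotypes. Of 19 abscisic acid genes, 4 rose, 5 fell and 10 were not called (4 and 5 adjusted over the list alone). The median was -0.26 (adjusted p = 0.818, 0.971 with an estimated correlation). Their mean was 0.08 and the test was directed downward. The number that fell was 3 without Col-0 control replicate 2, Col-0 ozone replicate 1 or Col-0 ozone replicate 3. CYP707A3 (AT5G45340), which breaks down abscisic acid, rose by 2.22. Of 22 antioxidant enzymes, 8 rose, 7 fell and 7 were not called (9 and 7 adjusted over the list alone). The median was -0.13 (adjusted p = 0.846, 0.956 with an estimated correlation). Here the mean was 0.21 and the test was directed upward. GSH2 (AT5G27380), which completes glutathione, rose by 2.96. Of 17 phenylpropanoid and flavonoid genes, 6 rose, 7 fell and 4 were not called (6 and 7 adjusted over the list alone). The median was -0.57 (adjusted p = 0.825, 0.971 with an estimated correlation). With a mean of 0.02, that list also went both ways. PAL2 (AT3G53260), at the entry of the pathway, rose by 2.51, and TT4, chalcone synthase, which AT5G13940 overlaps, had -1.60. Of 16 clock genes, 2 rose, 6 fell and 8 were not called (2 and 5 adjusted over the list alone). The median was -0.20 (adjusted p = 0.217, 0.685 with an estimated correlation). COL2 (AT3G02380) was at -2.21 and TOC1 (AT5G61380) at 1.46. Of 21 guard cell genes, 3 rose, 10 fell and 8 were not called (3 and 10 adjusted over the list alone). The median was -0.27 (adjusted p = 0.0777, 0.481 with an estimated correlation). The blue-light receptor PHOT1 (AT3G45780) was at -1.79. MPK12 (AT2G46070), a guard cell MAP kinase, had 14.5 ± 1.41 CPM in controls and 14.5 ± 0.908 after ozone, a log2 fold change of 0.00 (SE 0.12, adjusted p = 0.995). Of 4 floral organ and flowering markers, 0 rose, 2 fell and 2 were not called (0 and 1 adjusted over the list alone). The median was -0.40 (adjusted p = 0.565, 0.705 with an estimated correlation). AG (AT4G18960), a floral identity gene, had 1.96 and 0.528 CPM. Of these markers, 1 fell without any 1 of 8 libraries. The only tested root marker, NRT2.1 (AT1G08090), a nitrate carrier, had 0.353 and 0.302 CPM and was not called (-0.11, adjusted p = 0.942, 0 adjusted over the list alone). Of 8 reference genes, 3 rose, 0 fell and 5 were not called (3 and 0 adjusted over the list alone). The median was 0.14 (adjusted p = 0.346, 0.685 with an estimated correlation). UBQ10 (AT4G05320), a polyubiquitin, was at 2.05 and ACT2 (AT3G18780) at 0.51, and 5 rose without Col-0 ozone replicate 2.

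In the sensitive accession Cvi-0 the same exposure raised most tested genes of the salicylic acid, reactive oxygen and heat shock lists. It lowered every tested gene of the photosynthesis list. ICS1 (AT1G74710) went from 14.1 ± 0.833 to 1294 ± 294 CPM (SD, n = 3), and RBOHF (AT1G64060), an NADPH oxidase, from 29.6 ± 2.60 to 307 ± 54.8 CPM. RCA (AT2G39730) went down from 12482 ± 1065 to 3442 ± 205 CPM. edgeR called 7112 genes higher and 7438 lower, and 4755 and 3479 of them changed at least 2-fold. The direction with more calls turned with DESeq2 size factors (7414 higher, 7008 lower) and 4 other alternatives.

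The highest genes in Cvi-0 included AT1G13480, at least 2650.3-fold higher than in controls with no count, PP2-B6 (AT2G02310), an F-box gene, at least 846-fold, and RRTF1 (AT4G34410, which AT4G34412 overlaps), a redox-responsive factor, at least 1096-fold. YLS9 (AT2G35980), a gene of leaf senescence and defence, changed by 12.19 (SE 0.70, adjusted p = 1.0e-10). AT3G61390, a U-box gene with 3 counts over the controls, had a ratio of 4983 (95% interval 1705 to 24167). The lowest included SWEET13 (AT5G50800), a sugar carrier, at -6.04, TBL26 (AT4G01080) at -5.99 (SE 0.67, adjusted p = 4.1e-07), SAUR20 (AT5G18020) at -5.78, and AT5G05840, with 2 counts after ozone and 170.0-fold lower (46.8 to 1408).

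Of 19 salicylic acid genes, 17 rose, 0 fell and 2 were not called (17 and 0 adjusted over the list alone). In Cvi-0 their median was 3.88 (adjusted p = 4.1e-06, 0.447 with an estimated correlation). ICS1 (AT1G74710) was at 6.51 (SE 0.32, adjusted p = 1.5e-11), PAD4 (AT3G52430), a lipase-like defence regulator, at 3.88 and SAG101 (AT5G14930) at 5.05. Of 15 regulators that respond to reactive oxygen, 15 rose, 0 fell and 0 were not called (15 and 0 adjusted over the list alone). The median was 4.71 (adjusted p = 2.5e-08, 0.187 with an estimated correlation). RBOHF (AT1G64060) was at 3.38 (SE 0.17, adjusted p = 1.8e-11) and the kinase OXI1 (AT3G25250) at 10.84. Of 20 WRKY factors, 20 rose, 0 fell and 0 were not called (20 and 0 adjusted over the list alone). The median was 5.24 (adjusted p = 1.2e-09, 0.187 with an estimated correlation). WRKY25 (AT2G30250) was at 4.65. Of 17 heat shock genes, 15 rose, 0 fell and 2 were not called (15 and 0 adjusted over the list alone). The median was 4.43 (adjusted p = 4.1e-06, 0.272 with an estimated correlation). HSFA2 (AT2G26150) was at 6.95. Other lists that rose were calcium, touch and MAP kinase genes (3.32, adjusted p = 4.6e-07, 0.187 with an estimated correlation), ethylene genes (3.72, adjusted p = 6.2e-07, 0.187 with an estimated correlation) and jasmonate genes (2.50, adjusted p = 1.2e-04, 0.461 with an estimated correlation). Further ones were tryptophan and camalexin genes (3.64, adjusted p = 1.5e-08, 0.187 with an estimated correlation), glutathione transferases (4.26, adjusted p = 1.6e-04, 0.311 with an estimated correlation) and receptor-like kinases (2.31, adjusted p = 1.7e-04, 0.303 with an estimated correlation). Their members included MPK11 (AT1G01560) at 7.96, ERF1A (AT4G17500), an ethylene response factor, at 6.98, AOC3 (AT3G25780), an enzyme of jasmonate synthesis, at 7.41, GSTU12 (AT1G69920) at 10.11 and CRK13 (AT4G23210) at 9.52.

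Of 36 photosynthesis genes, 0 rose, 36 fell and 0 were not called (0 and 36 adjusted over the list alone). In Cvi-0 this median was -1.27 (adjusted p = 1.2e-09, 0.461 with an estimated correlation). RCA (AT2G39730) was at -1.86 (SE 0.16, adjusted p = 1.4e-08) and PSBX (AT2G06520), of photosystem II, at -1.69. Of 18 glucosinolate genes, 0 rose, 16 fell and 2 were not called (0 and 16 adjusted over the list alone). The median was -1.98 (adjusted p = 4.1e-06, 0.311 with an estimated correlation). MYB28 (AT5G61420) was at -2.93 and ESM1 (AT3G14210), which steers glucosinolate breakdown, at -2.99. Of 21 auxin and cell expansion genes, 3 rose, 16 fell and 2 were not called (3 and 16 adjusted over the list alone). The median was -1.71 (adjusted p = 0.00114, 0.444 with an estimated correlation). The expansin EXPA11 (AT1G20190) was at -4.30. Of 12 senescence and cell death genes, 9 rose, 3 fell and 0 were not called (9 and 3 adjusted over the list alone). The median was 2.18 (adjusted p = 0.0987, 0.0475 with the replicate block, 4.8e-07 with fry, 0.447 with an estimated correlation). BAP2 (AT2G45760), an inhibitor of cell death, was at 8.35 and SAG29 (AT5G13170) at -5.48. MPK12 (AT2G46070) had 15.2 ± 0.788 and 15.7 ± 1.83 CPM, a log2 fold change of 0.05 (SE 0.12, adjusted p = 0.741).

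In the near-isogenic line Col-S, ozone raised most salicylic acid, reactive oxygen, heat shock and WRKY genes and lowered most photosynthesis, auxin and glucosinolate genes. ICS1 (AT1G74710) went from 21.4 ± 2.04 to 961 ± 155 CPM, PAD4 (AT3G52430) from 20.8 ± 1.96 to 294 ± 28.6 CPM and RCA (AT2G39730) from 12623 ± 900.3 to 4757 ± 629 CPM (SD, n = 3). edgeR called 7076 genes higher and 7005 lower, of which 4577 and 2788 changed at least 2-fold. With the replicate block 7379 were higher and 7482 lower.

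At the top were PER4 (AT1G14540), a peroxidase, at 12.10 (SE 0.64, adjusted p = 3.7e-11), the lectin receptor kinase gene AT1G70130, at least 569.7-fold higher, CYP71A18 (AT1G11610), at least 461-fold, and the bHLH factor gene AT2G22760, at least 385-fold, the latter 3 with no count in controls. WRKY75 (AT5G13080), with 2 counts in controls, had a ratio of 3312 (95% interval 916 to 27352). At the bottom were AT1G29460, a small auxin-up RNA gene, at -6.67 (SE 0.50, adjusted p = 3.5e-09), GA20OX1 (AT4G25420), an enzyme of gibberellin synthesis, at -5.16, and AT5G05840 at -5.69.

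Of 19 salicylic acid genes, 18 rose, 0 fell and 1 was not called (18 and 0 adjusted over the list alone). In Col-S their median was 4.51 (adjusted p = 5.5e-07, 0.394 with an estimated correlation). ICS1 (AT1G74710) was at 5.49 (SE 0.30, adjusted p = 6.5e-11), PAD4 (AT3G52430) at 3.82 and SAG101 (AT5G14930) at 4.96. Of 15 reactive oxygen regulators, 15 rose, 0 fell and 0 were not called (15 and 0 adjusted over the list alone). The median was 4.93 (adjusted p = 3.7e-08, 0.187 with an estimated correlation). The zinc finger gene ZAT12 (AT5G59820) was at 9.09 (SE 0.49, adjusted p = 5.6e-11). Of 17 heat shock genes, 16 rose, 0 fell and 1 was not called (16 and 0 adjusted over the list alone). The median was 4.46 (adjusted p = 1.4e-06, 0.251 with an estimated correlation). HSP70 (AT3G12580) was at 5.56 (SE 0.28, adjusted p = 2.6e-11). Of 36 photosynthesis genes, 0 rose, 36 fell and 0 were not called (0 and 36 adjusted over the list alone). The median was -0.98 (adjusted p = 1.3e-08, 0.461 with an estimated correlation). LHCB5 (AT4G10340), a light-harvesting protein, was at -1.14. Of 21 auxin and cell expansion genes, 1 rose, 17 fell and 3 were not called (1 and 17 adjusted over the list alone). The median was -2.18 (adjusted p = 1.0e-05, 0.301 with an estimated correlation). PIN3 (AT1G70940) was at -2.87. Among 18 glucosinolate genes, 2 rose, 14 fell and 2 were not called (2 and 15 adjusted over the list alone). The median was -1.70 (adjusted p = 3.2e-05, 0.394 with an estimated correlation). The number that rose ranged from 0 to 2 over the libraries left out, and BAT5 (AT4G12030), a carrier of glucosinolate synthesis, was at -1.65. Other lists that rose were WRKY factors (5.53, adjusted p = 4.7e-10, 0.187 with an estimated correlation), calcium, touch and MAP kinase genes (3.52, adjusted p = 1.3e-07, 0.187 with an estimated correlation), ethylene genes (3.70, adjusted p = 3.3e-06, 0.187 with an estimated correlation) and jasmonate genes (3.41, adjusted p = 4.2e-05, 0.461 with an estimated correlation). Further ones were glutathione transferases (3.95, adjusted p = 1.0e-04, 0.307 with an estimated correlation), receptor-like kinases (3.85, adjusted p = 2.9e-06, 0.213 with an estimated correlation), tryptophan and camalexin genes (3.11, adjusted p = 5.5e-07, 0.189 with an estimated correlation) and senescence genes (2.01, adjusted p = 0.0341, 0.311 with an estimated correlation). Their members included MPK3 (AT3G45640) at 3.52, CML38 (AT1G76650) at 7.57, AOC3 (AT3G25780) at 7.68, CYP71A12 (AT2G30750) at 10.25 and MC8 (AT1G16420) at 6.91. MPK12 (AT2G46070) had 14.6 ± 2.24 and 12.9 ± 0.289 CPM, a log2 fold change of -0.18 (SE 0.12, adjusted p = 0.194).

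**Figure D2:**
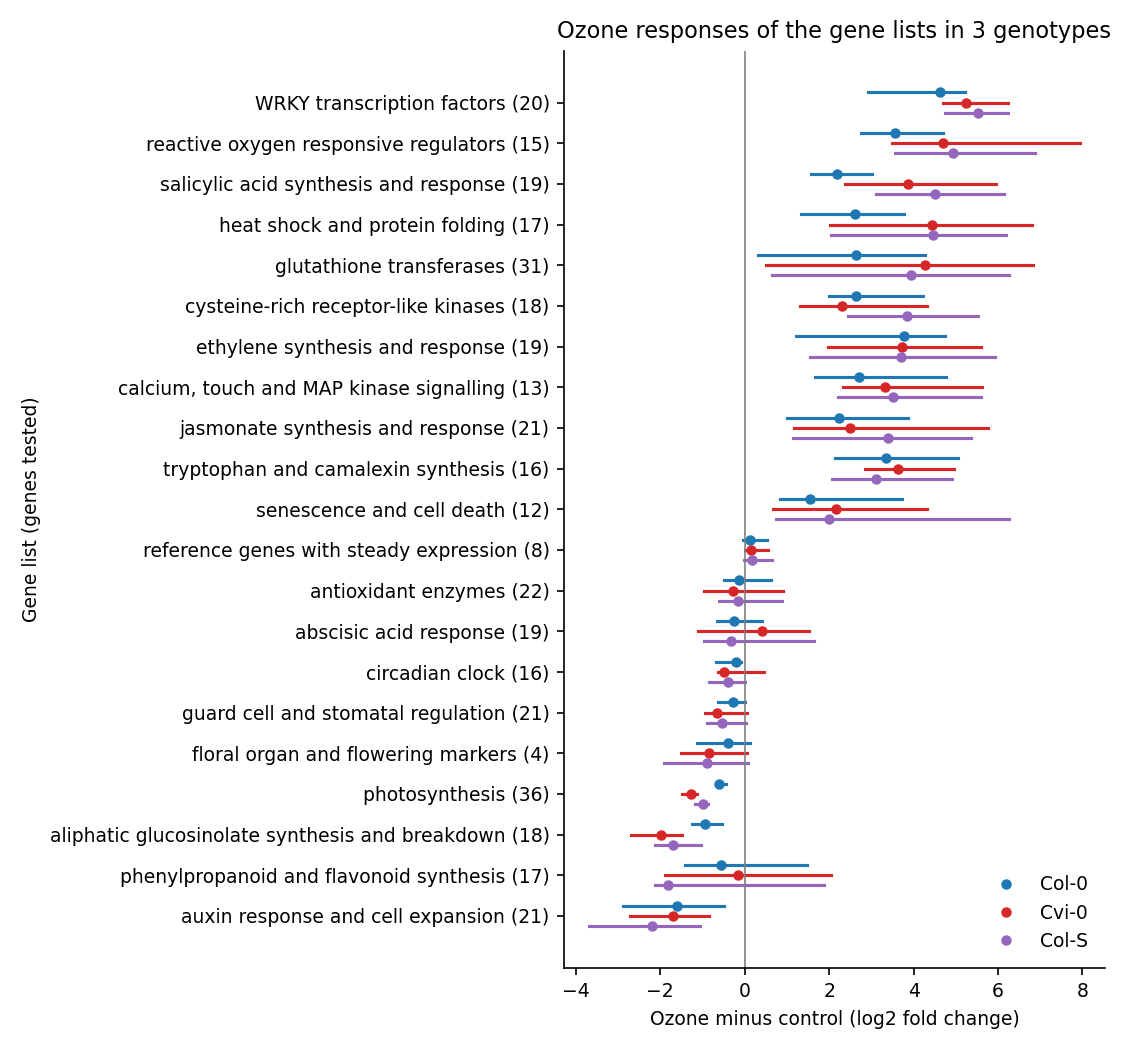
Median log2 fold change (x axis) of each of 21 gene lists after ozone, by genotype, where points are medians and bars run between the quartiles of the list. The salicylic acid list has medians of 2.18 in Col-0, 3.88 in Cvi-0 and 4.51 in Col-S, and the photosynthesis list of -0.60, -1.27 and -0.98.

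Across genotypes, 5176 genes were higher and 4822 lower after ozone in all 3. Col-S shared 5748 of the 6145 genes called higher in Col-0, or 93.5%, where independent lists would share 2108.5, and 5234 of the 5679 called lower, or 92.2%. Cvi-0 shared 5274 of the former (85.8%) and 4981 of the latter (87.7%). Of 10997 genes called in both Col-S and Col-0, 15 went in opposite directions, against 171 of 10426 for Cvi-0 and Col-0. Over 16238 genes the log2 response was 1.35 times as large in Col-S as in Col-0 (jackknife SE 0.141, 12 libraries), 1.44 times as large in Cvi-0 as in Col-0 (SE 0.149) and 0.960 times as large in Col-S as in Cvi-0 (SE 0.0386). The median absolute log2 fold change was 0.67 in Col-0, 1.00 in Cvi-0 and 0.90 in Col-S. Across these genes, which are not independent replicates, Pearson's r was 0.935 for Col-S and Col-0 and 0.940 for Col-S and Cvi-0.

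The difference between the responses of Col-S and Col-0 asked which part of the reaction to ozone changed with the introgression. camera called the lists of salicylic acid genes, reactive oxygen regulators, calcium and MAP kinase genes, WRKY factors and heat shock genes as higher in Col-S, but none with an estimated correlation. Of their genes, 9 of 19, 5 of 15, 5 of 13, 5 of 20 and 4 of 17 were called, and these counts depended on single libraries. ICS1 (AT1G74710) reached 961 ± 155 CPM after ozone in Col-S and 263 ± 36.2 in Col-0, and PAD4 (AT3G52430), which lies at chromosome 3, 19431371 to 19434403, reached 294 ± 28.6 and 87.0 ± 7.34 CPM (SD, n = 3). The differences of the log2 responses were 2.33 (SE 0.36, adjusted p = 0.00263) for ICS1, 2.29 (SE 0.30, adjusted p = 0.00136) for PAD4, 1.97 for SAG101 (AT5G14930) and 3.07 (SE 0.53, adjusted p = 0.00490) for PBS3 (AT5G13320), an enzyme of salicylic acid synthesis. edgeR called 606 genes with a higher and 67 with a lower response in Col-S, 444 and 32 of them by at least 2-fold. With the replicate block the counts were 1058 and 424, with only the groups compared in the fit 263 and 16, and with the DESeq2 Wald test 1128 and 158.

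The total of 673 was 304 without Col-S control replicate 3, 307 without Col-0 control replicate 2, 328 without Col-0 ozone replicate 2, 339 without Col-S ozone replicate 3, 372 without Col-S control replicate 1, 421 without Col-S control replicate 2 and 1308 without Col-S ozone replicate 2. Of the 606, 496 also rose in Col-0 and 593 rose in Col-S, with median log2 fold changes of 1.65 and 3.33. Of the 43 called genes named by the rule, 13 were called without each library in turn. They included ZAT7 (AT3G46090), a zinc finger gene that responds to oxidative stress, with a difference of 4.48 (SE 0.55, adjusted p = 6.1e-04), RBOHF (AT1G64060) with 1.49 (SE 0.22, adjusted p = 0.00228), TCH4 (AT5G57560), a cell wall enzyme that responds to touch, with 2.71 (SE 0.36, adjusted p = 0.00137), and LSD1 (AT4G20380), which restrains cell death, with 1.28 (SE 0.24, adjusted p = 0.00711). HSP101 (AT1G74310, which AT1G74300 overlaps), a chaperone, had 2.17 (SE 0.34, adjusted p = 0.00263). Lower responses in Col-S were those of AT3G49970, of a family of phototropic signalling, with -2.79 (SE 0.41, adjusted p = 0.00208), and AT2G39710, a protease gene, with -1.71, both inside the stretches described with the controls.

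In the salicylic acid list, 9 of 19 genes had a higher response in Col-S, 0 a lower one and 10 were not called (15 and 0 adjusted over the list alone), with a median difference of 2.29 (adjusted p = 1.1e-10, 0.253 with an estimated correlation). The 9 were 4 without Col-0 control replicate 2 and 5 without Col-S control replicate 1, and the median was 1.55 without Col-0 control replicate 2. In that library FMO1 (AT1G19250) stood at 8.92 CPM against 0.412 and 0.877 in the other Col-0 controls, ALD1 (AT2G13810) at 20.5 against 0.824 and 3.41, and ICS1 at 46.6 against 21.5 and 19.8. For FMO1, an enzyme of systemic resistance, the response difference of 6.63 (adjusted p = 0.00973) was 4.18 (adjusted p = 0.0520) without it. Comparing ozone libraries alone, the median of the list was 0.98 higher in Col-S than in Col-0.

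**Figure D3:**
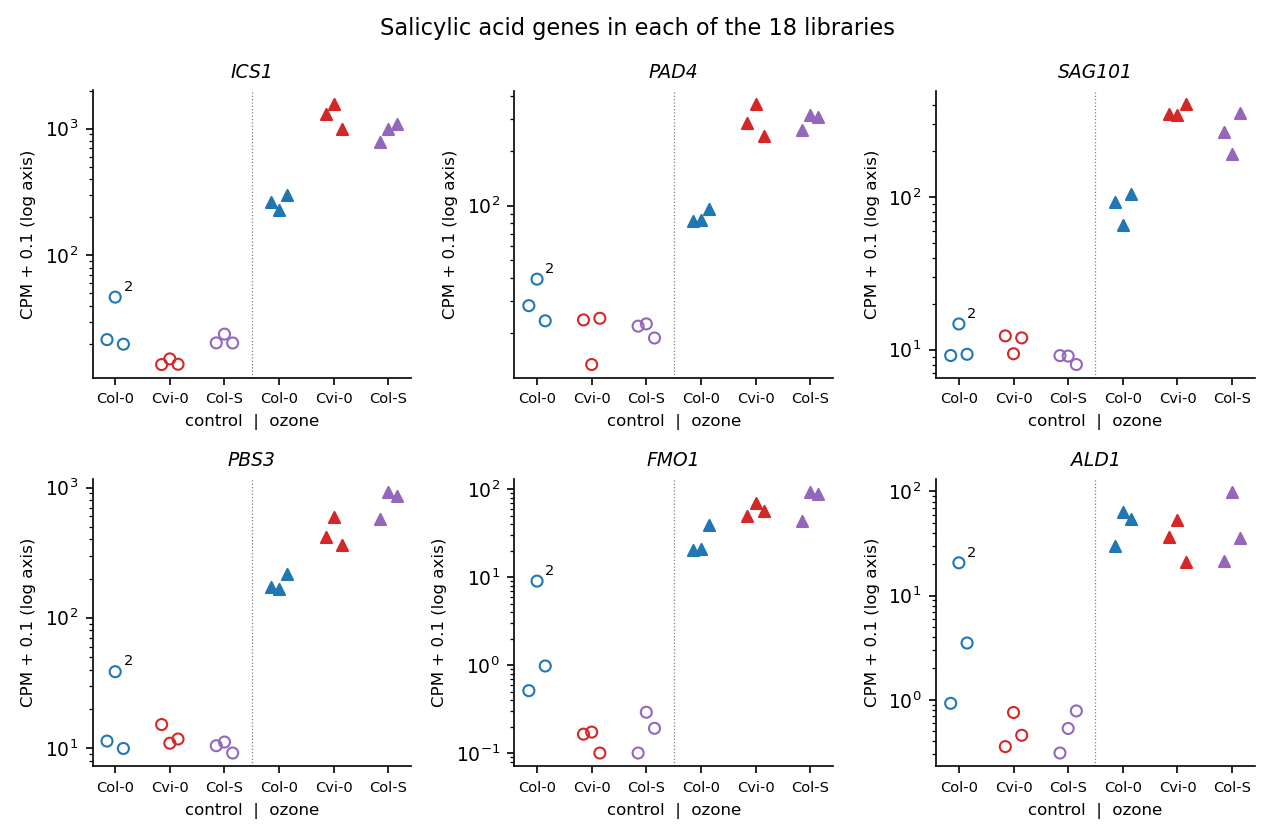
CPM plus 0.1 (y axis, log scale) of ICS1, PAD4, SAG101, PBS3, FMO1 and ALD1 in each library, by genotype and treatment, 1 point per library. Col-0 control replicate 2, marked 2, lies above the other Col-0 controls for FMO1 (8.92 against 0.412 and 0.877) and ALD1 (20.5 against 0.824 and 3.41).

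Of 15 reactive oxygen regulators, 5 responded more, 0 less and 10 were not called (8 and 0 adjusted over the list alone). The median was 0.96 (adjusted p = 1.6e-08, 0.187 with an estimated correlation). The 5 were 2 without Col-0 control replicate 2. They were 3 without any 1 of Col-0 control replicate 1, Col-0 ozone replicates 1 and 2, the 3 Cvi-0 ozone libraries, Col-S control replicates 2 and 3, and Col-S ozone replicate 3. Of 13 calcium, touch and MAP kinase genes, 5 responded more, 0 less and 8 were not called (9 and 0 adjusted over the list alone). The median was 0.59 (adjusted p = 2.2e-07, 0.187 with an estimated correlation). These 5 were 1 without Col-S control replicate 3, and 3 without Col-0 ozone replicate 1. They were 2 without Col-0 control replicate 2, Col-0 ozone replicate 2, Col-S control replicate 1 or Col-S ozone replicate 3. Of 20 WRKY factors, 5 responded more, 0 less and 15 were not called (11 and 0 adjusted over the list alone). The median was 1.11 (adjusted p = 2.3e-06, 0.303 with an estimated correlation). That 5 was 0 without Col-0 ozone replicate 2. It was 1 without Col-0 control replicate 2, Col-0 ozone replicate 1, Col-S control replicate 1 or 3, or Col-S ozone replicate 3. Of 17 heat shock genes, 4 responded more, 0 less and 13 were not called (8 and 0 adjusted over the list alone). The median was 1.21 (adjusted p = 2.9e-08, 0.187 with an estimated correlation). The 4 were 1 without Col-0 control replicate 2, and 2 without Col-0 ozone replicate 2 or Col-S control replicate 3. Of 18 glucosinolate genes, 0 responded more, 1 less and 17 were not called (0 and 6 adjusted over the list alone). The median was -0.61 (adjusted p = 6.4e-07, 0.303 with an estimated correlation). The 1 was BAT5 (AT4G12030), a carrier of glucosinolate synthesis, at -0.91 (adjusted p = 0.0291). The count was 6 without Col-S ozone replicate 2. It was 0 without Col-0 control replicate 2 or 3, Col-0 ozone replicate 2, Col-S control replicate 1 or 2, or Col-S ozone replicate 1 or 3. These list calls, and that of the salicylic acid list, held under fry and without each library.

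Of 36 photosynthesis genes, 0 responded more, 0 less and 36 were not called (0 and 0 adjusted over the list alone). The list was called by camera, not by fry (adjusted p = 0.0596), with a median of -0.43 (adjusted p = 7.2e-10, 0.461 with an estimated correlation). The member with the smallest p was RBCS2B (AT5G38420), a small subunit of Rubisco, at -0.57 (SE 0.19, adjusted p = 0.115). Of 21 jasmonate genes, 2 responded more, 1 less and 18 were not called (12 and 3 adjusted over the list alone). The median was 0.94 (adjusted p = 0.00164, 0.565 with an estimated correlation). The list adjusted p was 0.177 with fry and 0.0556 without Col-0 ozone replicate 1. Of 31 glutathione transferases, 2 responded more, 0 less and 29 were not called (5 and 1 adjusted over the list alone). The median was 0.77 (adjusted p = 0.00646, 0.461 with an estimated correlation). That list had an adjusted p of 0.0802 with fry and 0.0531 without Col-0 control replicate 2. Of 18 receptor-like kinases, 3 responded more, 0 less and 15 were not called (6 and 0 adjusted over the list alone). The median was 0.56 (adjusted p = 0.00646, 0.461 with an estimated correlation). With fry the adjusted p was 0.0886. Of 21 auxin and cell expansion genes, 1 responded more, 1 less and 19 were not called (1 and 1 adjusted over the list alone). The median was -0.46 (adjusted p = 0.00710, 0.461 with an estimated correlation). The list adjusted p was 0.183 with fry, 0.0794 without Col-0 ozone replicate 2 and 0.0522 without Col-S control replicate 1. Over the libraries left out, the jasmonate, glutathione transferase and receptor-like kinase genes that responded more ranged from 0 to 9, 0 to 4 and 0 to 5. Ethylene genes (median 0.26, adjusted p = 0.205, 0.637 with an estimated correlation) and tryptophan and camalexin genes (0.04, adjusted p = 0.914, 0.973 with an estimated correlation) were not called as lists, but the ethylene list was called without Col-0 control replicate 2 (adjusted p = 0.0403). Phenylpropanoid genes (median -0.74, adjusted p = 0.122, 0.685 with an estimated correlation) were called with the replicate block (0.0149) and without Col-0 control replicate 2 (0.0421), Col-0 ozone replicate 1 (0.0321) or Col-S ozone replicate 3 (0.0216). MPK12 (AT2G46070) had a difference of -0.18 (SE 0.17, adjusted p = 0.624).

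The responses of Cvi-0 and Col-0 differed in more genes, with the same limit on list calls. By camera, though not with an estimated correlation, the lists of salicylic acid and reactive oxygen genes were higher in Cvi-0 and those of photosynthesis and glucosinolate genes lower. RBOHF (AT1G64060) rose to 307 ± 54.8 CPM in Cvi-0 and stood at 27.4 ± 4.49 in Col-0 after ozone (difference 2.82, SE 0.22, adjusted p = 7.2e-07), and CRK13 (AT4G23210), a receptor-like kinase, reached 1238 ± 99.3 and 165 ± 41.4 CPM (difference 4.87, SE 0.39, adjusted p = 8.8e-07). CRK29 (AT4G21410), of the same family, reached 17.7 ± 2.43 and 112 ± 36.8 CPM (difference -2.69, SE 0.35, adjusted p = 7.3e-05). edgeR called 2288 genes with a higher and 2115 with a lower response in Cvi-0, 1411 and 781 of them by at least 2-fold. The direction with more calls depended on processing, with 2824 higher and 3181 lower with the replicate block and 2471 and 1749 with DESeq2 size factors. Of the 2288, 2124 rose in Cvi-0 and 1434 in Col-0.

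Of 19 salicylic acid genes, 10 responded more, 0 less and 9 were not called (10 and 0 adjusted over the list alone). The median difference was 2.00 (adjusted p = 1.2e-05, 0.461 with an estimated correlation). ICS1 (AT1G74710) was at 3.35 (SE 0.37, adjusted p = 1.7e-05) and PAD4 (AT3G52430) at 2.35. Of 15 reactive oxygen regulators, 9 responded more, 1 less and 5 were not called (9 and 1 adjusted over the list alone). The median was 1.44 (adjusted p = 5.9e-07, 0.189 with an estimated correlation). ZAT7 (AT3G46090) was at 5.43 (SE 0.55, adjusted p = 7.6e-06) and BAP1 (AT3G61190), an inhibitor of cell death, at 4.15. Of 20 WRKY factors, 8 responded more, 1 less and 11 were not called (8 and 1 adjusted over the list alone). The median was 0.99 (adjusted p = 0.00111, 0.461 with an estimated correlation). WRKY22 (AT4G01250) was at 3.58, and 5 factors responded more without Col-0 control replicate 2. Of 13 calcium, touch and MAP kinase genes, 6 responded more, 1 less and 6 were not called (7 and 1 adjusted over the list alone). The median was 0.60 (adjusted p = 0.00173, 0.417 with an estimated correlation). TCH4 (AT5G57560) was at 3.49. The number of genes that responded less in the reactive oxygen, WRKY and calcium lists ranged from 0 to 1 over the libraries left out. Of 17 heat shock genes, 7 responded more, 0 less and 10 were not called (8 and 0 adjusted over the list alone). Their list adjusted p was 4.1e-05 (0.303 with an estimated correlation). HSFA2 (AT2G26150) was at 1.28, and 3 genes responded more without Col-0 control replicate 2. Of 16 tryptophan and camalexin genes, 5 responded more, 0 less and 11 were not called (7 and 0 adjusted over the list alone). The median was 0.24 (adjusted p = 0.0324, 0.528 with an estimated correlation). CYP79B2 (AT4G39950), which turns tryptophan into an oxime, was at 3.72 (SE 0.37, adjusted p = 6.4e-06). That list call ended without Col-0 control replicate 2 (adjusted p = 0.127), Col-0 ozone replicate 2 (0.0762), Cvi-0 control replicate 2 (0.104) or Cvi-0 ozone replicate 2 (0.0663).

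Of 36 photosynthesis genes, 0 responded more, 29 less and 7 were not called (0 and 34 adjusted over the list alone). The median was -0.72 (adjusted p = 8.2e-10, 0.461 with an estimated correlation). RCA (AT2G39730) was at -1.05 (SE 0.22, adjusted p = 0.00264), and the 29 genes were 19 without Cvi-0 ozone replicate 3. Of 18 glucosinolate genes, 0 responded more, 12 less and 6 were not called (0 and 13 adjusted over the list alone). The median was -1.16 (adjusted p = 5.5e-07, 0.303 with an estimated correlation). MYB28 (AT5G61420) was at -1.53 and BAT5 (AT4G12030) at -1.97 (SE 0.22, adjusted p = 1.8e-05). Of 21 jasmonate genes, 6 responded more, 3 less and 12 were not called (9 and 3 adjusted over the list alone). The median was 0.89 (adjusted p = 0.0409, 0.705 with an estimated correlation). LOX3 (AT1G17420) was at 1.96 and AOC1 (AT3G25760) at -2.48, both enzymes of jasmonate synthesis, and 10 genes responded more without Col-0 ozone replicate 3. The jasmonate list call ended with fry (adjusted p = 0.210), and without Col-0 control replicate 2 (adjusted p = 0.0658) or 3 (0.0533), Col-0 ozone replicate 1 (0.175) or 2 (0.0693), Cvi-0 control replicate 2 (0.0801), Cvi-0 ozone replicate 3 (0.0820) or Col-S control replicate 2 (0.0504). Of 22 antioxidant genes, 1 responded more, 7 less and 14 were not called (1 and 8 adjusted over the list alone). The median was -0.36 (adjusted p = 0.0542, 0.0372 with the replicate block, 0.00180 with fry, 0.311 with an estimated correlation), and the list was called without any 1 of 6 libraries (0.0264 to 0.0482). The 7 were 4 without Col-0 control replicate 3, and the 1 was 2 without Col-S ozone replicate 2. GSH2 (AT5G27380) had -1.94 (SE 0.25, adjusted p = 6.4e-05). GPX2, a peroxidase gene that AT2G31560 overlaps, had 1.68 (SE 0.14, adjusted p = 1.7e-06). Of 19 ethylene genes, 5 responded more, 2 less and 12 were not called (6 and 2 adjusted over the list alone), and 1 to 2 responded less over the libraries left out. The median was 0.28 (adjusted p = 0.0793, 0.0341 with fry, 0.461 with an estimated correlation). The list was called without Col-0 control replicate 2 (0.0197) or Cvi-0 control replicate 3 (0.0125). The factor ORA59 (AT1G06160) had -2.68, and MPK12 (AT2G46070) had 0.04 (SE 0.17, adjusted p = 0.887).

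Both differences against Col-0 used the same Col-0 libraries. They shared 518 genes with a higher and 52 with a lower response, where independent lists would share 67.2 and 6.87. Across all genes the covariance of the 2 differences was 0.613 (r 0.683). It was 0.139 on average (r 0.549) in 10 simulations that gave each genotype the same log2 ozone response and shared the Col-0 libraries. The simulations called 0.1 and 0 genes on average, so that their overlap of 0 says nothing about the shared calls. Part of the excess of shared calls may come from the shared libraries.

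Col-S and Cvi-0, both sensitive, differed in the responses of 1003 genes, fewer than the 4403 for Cvi-0 and Col-0. Their order with the 673 for Col-S and Col-0 depended on 1 library, with 876 and 1308 genes without Col-S ozone replicate 2, and with the replicate block the counts were 1522 and 1482. CYP79B2 (AT4G39950) and CYP79B3 (AT2G22330) rose in Cvi-0 from 15.2 ± 2.55 to 368 ± 26.7 and from 19.2 ± 1.33 to 104 ± 7.16 CPM. In Col-S they stood at 173 ± 69.5 and 64.2 ± 15.3 CPM after ozone. The differences, mostly from higher Col-S controls, were -3.19 (SE 0.37, adjusted p = 5.8e-05) and -2.90 (SE 0.28, adjusted p = 8.6e-06). CRK13 (AT4G23210) responded less in Col-S, with -3.16 (SE 0.39, adjusted p = 1.1e-04), as did RBOHF (AT1G64060), with -1.33, and GPX2, which AT2G31560 overlaps, with -1.36. CRK29 (AT4G21410) responded more, with 2.46 (SE 0.35, adjusted p = 4.5e-04), as did AOC1 (AT3G25760), with 2.25, and GSH2 (AT5G27380), with 1.60. edgeR called 549 genes with a higher and 454 with a lower response in Col-S, 354 and 298 of them by at least 2-fold. The counts were 879 and 643 with the replicate block and 372 and 388 without Cvi-0 ozone replicate 3.

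Of 16 tryptophan and camalexin genes, 0 responded more, 3 less and 13 were not called (1 and 4 adjusted over the list alone). The median was -0.32 (adjusted p = 0.00184, 0.437 with an estimated correlation). This was the only 1 of 7 list calls of the comparison that held under fry. Of 18 receptor-like kinases, 5 responded more, 1 less and 12 were not called (6 and 1 adjusted over the list alone). The median was 0.60 (adjusted p = 0.0152, 0.461 with an estimated correlation). Of 18 glucosinolate genes, 3 responded more, 0 less and 15 were not called (3 and 1 adjusted over the list alone). The median was 0.42 (adjusted p = 0.00210, 0.461 with an estimated correlation). MYB28 (AT5G61420) was at 1.03 (SE 0.16, adjusted p = 0.00104) and ESM1 (AT3G14210) at 0.93. These calls and that of photosynthesis (median 0.26, adjusted p = 0.00127, 0.705 with an estimated correlation) held without each library. The reactive oxygen list (median -0.51, adjusted p = 0.0179, 0.461 with an estimated correlation) was not called without Cvi-0 control replicate 2 (adjusted p = 0.0861), Col-S control replicate 2 (0.0733) or Col-S ozone replicate 2 (0.0837). Auxin genes (median -0.17, adjusted p = 0.0299, 0.562 with an estimated correlation) were not called as a list without Cvi-0 control replicate 2 (0.0573), Col-S control replicate 1 (0.122) or Col-S ozone replicate 1 (0.0538). Phenylpropanoid and flavonoid genes (median -0.26, adjusted p = 0.0354, 0.565 with an estimated correlation) were not without Cvi-0 control replicate 1 (0.0800), Cvi-0 ozone replicate 2 (0.214) or 3 (0.0514), Col-S control replicate 2 (0.151) or Col-S ozone replicate 1 (0.132) or 2 (0.0559). The salicylic acid list had a median of 0.27 (adjusted p = 0.882, 0.973 with an estimated correlation), and MPK12 (AT2G46070) had -0.23 (SE 0.17, adjusted p = 0.572).

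The controls of Col-S and Col-0 compared the line with its background accession without ozone. Genes on chromosomes 2 and 3 stood out, and at many of them Col-S resembled Cvi-0. AT2G43960, which encodes a protein with a SWAP domain (chromosome 2, 18203312 to 18204912), had no count in Col-0 controls, 35.6 ± 3.50 CPM in Col-S and 34.9 ± 0.506 CPM in Cvi-0, and was at least 718-fold higher in Col-S. HR4 (AT3G50480), a homolog of a mildew resistance gene (chromosome 3, 18733068 to 18734388), had 87.9 ± 80.9 CPM in Col-0, 0.577 ± 0.306 in Col-S and 0.226 ± 0.0263 in Cvi-0, a log2 fold change of -7.27 (SE 0.62, adjusted p = 2.5e-06), or -6.18 without Col-0 control replicate 2, where it stood at 181 CPM against 33.5 and 49.4. AT3G47680 had 1 count in Col-S controls and was 1308-fold lower (95% interval 234 to 51717), and AT2G41440, a MADS-box gene, had 2 counts and was 146-fold lower (40.1 to 1213). AT3G47580, a receptor kinase gene that AT3G47590 overlaps, had -6.93, AT2G45930 had 4.33 (SE 0.28, adjusted p = 8.8e-08) and AT3G48640 2.70 (SE 0.38, adjusted p = 8.6e-04). AT3G48640 rose to 572 ± 54.9 CPM after ozone in Col-S, 543 ± 79.4 in Cvi-0 and 30.5 ± 7.08 in Col-0.

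edgeR called 70 genes higher and 104 lower in Col-S, 49 and 77 of them by at least 2-fold, and the total of 174 was 105 with only the groups compared in the fit, 285 with the DESeq2 Wald test, 98 without Col-S control replicate 1, 104 without Col-S control replicate 2, 108 without Col-S control replicate 3 and 113 without Col-0 control replicate 2. Of 2296 called genes that differed at least 2-fold between Cvi-0 and Col-0 controls, 250 (10.9%) lay nearer to Cvi-0 in Col-S, and 7 of 114 tested bins held more of them than the rest of the genome. These bins formed 2 stretches. On chromosome 2 from 16 to 19 Mb, 47 of 60 such genes were Cvi-like (78.3%, exact 95% interval 65.8% to 87.9%), and on chromosome 3 from 17 to 21 Mb, 56 of 86 (65.1%, 54.1% to 75.1%). Outside, 147 of 2150 were Cvi-like (6.84%). Without Col-0 control replicate 1 or any 1 of the 3 Cvi-0 controls an eighth bin, on chromosome 3 from 21 to 22 Mb, was also called. The stretches, which were found with the same Col-S and Col-0 controls, held 110 of the 174 control calls and 74 of the 673 genes with a different response. MPK12 (chromosome 2, 18945981 to 18947823) lies in the chromosome 2 stretch, and its control level in Col-S was 14.6 ± 2.24 CPM (log2 fold change to Col-0 0.01, SE 0.12, adjusted p = 1.00). PAD4 and HR4 lie in the chromosome 3 stretch.

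**Figure D4:**
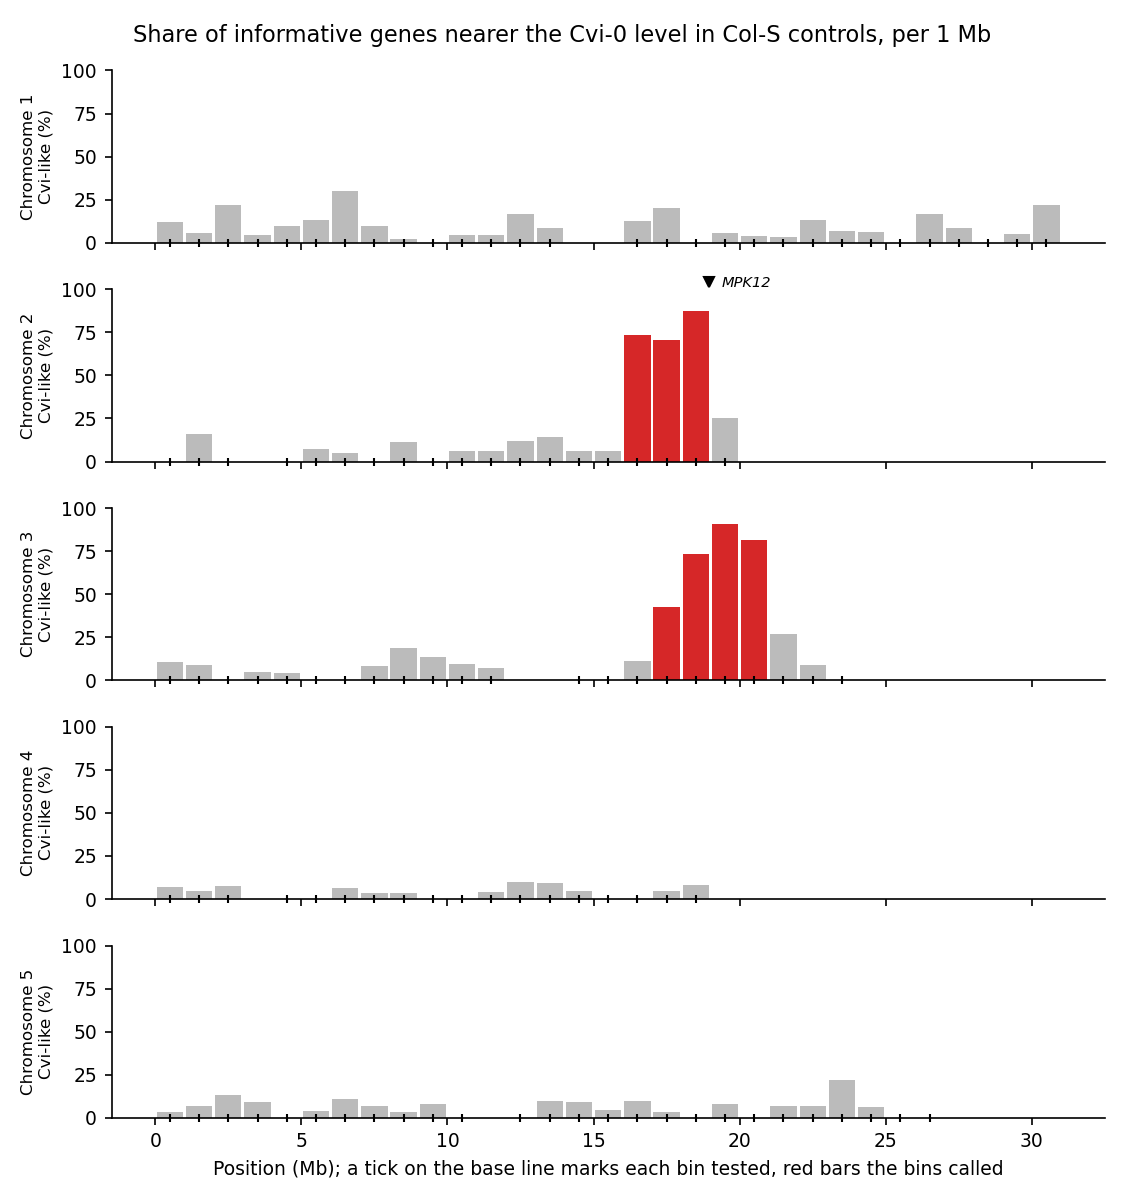
Percent of informative genes that were Cvi-like in Col-S controls (y axis) in bins of 1 Mb along the 5 chromosomes (x axis, Mb), with called bins in red and an arrow at MPK12. Called bins lie on chromosome 2 from 16 to 19 Mb and on chromosome 3 from 17 to 21 Mb.

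As a list, salicylic acid genes were lower in Col-S than in Col-0 controls (median -0.84, adjusted p = 1.6e-08, 0.308 with an estimated correlation) with 0 of 19 called (0 and 5 adjusted over the list alone), and the median was -0.18 without Col-0 control replicate 2. Abscisic acid genes were higher (2 of 19 called, 3 and 0 adjusted over the list alone, adjusted p = 5.2e-07, 0.251 with an estimated correlation). The 2 were 1 without Col-0 control replicate 2 or Col-S control replicate 3 and 0 without Col-0 control replicate 1 or 3 or Col-S control replicate 1 or 2. Reactive oxygen regulators (0 of 15 called, 0 and 2 adjusted over the list alone, adjusted p = 0.00342, 0.447 with an estimated correlation) and calcium, touch and MAP kinase genes (0 of 13 called, adjusted p = 0.00342, 0.447 with an estimated correlation) were lower. Glutathione transferases (adjusted p = 0.0278, 0.522 with an estimated correlation) were not called with the replicate block (adjusted p = 0.0624) or without Col-0 control replicate 2 (0.790) or Col-S control replicate 1 (0.120) or 3 (0.0578). Photosynthesis genes (adjusted p = 0.00254, 0.706 with an estimated correlation) were not called as a list without Col-0 control replicate 1 (0.175) or Col-S control replicate 3 (0.148), and auxin genes (adjusted p = 0.0333, 0.565 with an estimated correlation) without Col-0 control replicate 2 (0.146) or 3 (0.280) or Col-S control replicate 1 (0.439). Phenylpropanoid genes (adjusted p = 0.0777, 0.656 with an estimated correlation) were called with the replicate block (0.00538). They, and the ethylene, WRKY, receptor-like kinase, tryptophan and reference gene lists, were called without at least 1 of the libraries. None of the 7 list calls of this comparison held under fry, where the adjusted p ranged from 0.0722 for abscisic acid genes to 0.449 for photosynthesis.

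In controls of the parents Cvi-0 and Col-0, glucosinolate and flavonoid list calls held without each library, but not with an estimated correlation. ESM1 (AT3G14210) had 26.3 ± 3.15 CPM in Cvi-0 and 1199 ± 147 in Col-0 (log2 fold change -5.51, SE 0.16, adjusted p = 4.3e-13). The nitrile-forming gene AT1G54040 had 3749 ± 428 and 34.2 ± 0.943 CPM (log2 fold change 6.78, SE 0.34, adjusted p = 1.3e-10). FLC (AT5G10140), a repressor of flowering, had 26.7 ± 4.86 and 0.852 ± 0.165 CPM (log2 fold change 4.95, SE 0.24, adjusted p = 8.9e-11), and DFR (AT5G42800), of anthocyanin synthesis, 1.93 ± 1.09 and 47.2 ± 10.3 CPM (log2 fold change -4.53, SE 0.48, adjusted p = 1.5e-06). edgeR called 2515 genes higher and 2424 lower in Cvi-0, 1086 and 1210 of them at least 2-fold. With DESeq2 size factors 2342 were higher and 2551 lower, and 6 other alternatives also turned the direction with more calls. AT5G15360 was at least 860.3-fold higher and AT4G34881 at least 428-fold lower in Cvi-0, and AT4G16215, with 1 count in Col-0 controls, had a ratio of 9475 (95% interval 1700 to 3.7e+05). Lower counts in Cvi-0 may also come from reads lost in alignment.

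Of 18 glucosinolate genes, 13 were higher in Cvi-0, 1 lower and 4 were not called (13 and 1 adjusted over the list alone). The median was 0.81 (adjusted p = 4.7e-06, 0.313 with an estimated correlation). MAM3 (AT5G23020), which lengthens glucosinolate chains, was at 2.29 (SE 0.28, adjusted p = 9.0e-06). Of 17 phenylpropanoid and flavonoid genes, 0 were higher, 6 lower and 11 were not called (0 and 6 adjusted over the list alone). The median was -0.46 (adjusted p = 0.00337, 0.461 with an estimated correlation). LDOX (AT4G22880) was at -3.56 (SE 0.51, adjusted p = 5.2e-05) and TT8 (AT4G09820), its regulator, at -3.30. VSP1 (AT5G24780) and VSP2 (AT5G24770), storage proteins induced by jasmonate, had 3.09 (SE 0.29, adjusted p = 4.0e-07) and -3.53 (SE 0.41, adjusted p = 5.0e-06). Of 19 salicylic acid genes, 1 was higher, 7 lower and 11 were not called (1 and 8 adjusted over the list alone). The median was -0.69 (adjusted p = 0.0427, 0.705 with an estimated correlation). Without Col-0 control replicate 2, 2 were lower and the list adjusted p was 0.370. It was 0.198 with fry, 0.0693 without Col-0 ozone replicate 2, 0.137 without Cvi-0 control replicate 2 and 0.0630 without Cvi-0 ozone replicate 3. The list call of calcium genes (median -0.41, adjusted p = 0.0324, 0.522 with an estimated correlation) ended with fry (0.0524), and without Col-0 control replicate 2 (adjusted p = 0.0717) or Cvi-0 control replicate 2 (0.233). That of photosynthesis genes (median -0.20, adjusted p = 0.0372, 0.805 with an estimated correlation) ended with fry (0.316), and without Col-0 control replicate 1 (0.157) or Cvi-0 control replicate 2 (0.0922) or 3 (0.130). That of jasmonate genes (median 0.41, adjusted p = 0.0481, 0.705 with an estimated correlation) ended with fry (0.157), and without Col-0 control replicate 1 (0.116), Col-0 ozone replicate 1 (0.0543), Cvi-0 control replicate 1 (0.0770) or 3 (0.0823), Col-S control replicate 1 (0.0536) or Col-S ozone replicate 1 (0.0538). Reactive oxygen regulators had a median of -0.42, or -0.16 with the genes without counts set at their bound. MPK12 (AT2G46070) had 0.07 (SE 0.12, adjusted p = 0.744).

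Between the controls of Col-S and Cvi-0, camera called the glucosinolate, flavonoid and jasmonate lists, none with an estimated correlation. edgeR called 2105 genes higher and 2243 lower in Col-S, 1064 and 1008 of them at least 2-fold. With only the groups compared in the fit 2538 were higher and 2115 lower, and 5 other alternatives also turned the direction with more calls. Of 18 glucosinolate genes, 1 was higher in Col-S, 14 lower and 3 were not called (1 and 15 adjusted over the list alone). The median was -0.87 (adjusted p = 1.1e-06, 0.303 with an estimated correlation). ESM1 (AT3G14210) was at 5.22 (SE 0.16, adjusted p = 6.1e-13) and AT1G54040 at -6.49 (SE 0.34, adjusted p = 1.9e-10). Of 17 phenylpropanoid and flavonoid genes, 6 were higher, 1 lower and 10 were not called (9 and 1 adjusted over the list alone). The median was 0.64 (adjusted p = 2.0e-04, 0.333 with an estimated correlation). DFR (AT5G42800) was at 5.17. Of 21 jasmonate genes, 1 was higher, 4 lower and 16 were not called (1 and 7 adjusted over the list alone). The median was -0.49 (adjusted p = 0.0199, 0.0972 with fry, 0.685 with an estimated correlation). AOC2 (AT3G25770) was at -1.66 (SE 0.28, adjusted p = 2.9e-04), and 7 were lower without Col-S ozone replicate 2. FLC (AT5G10140) had 0.698 ± 0.221 CPM in Col-S controls, a log2 fold change of -5.23 (SE 0.25, adjusted p = 5.7e-11). MPK12 (AT2G46070) had -0.06 (SE 0.12, adjusted p = 0.802).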

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

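The tests of the salicylic acid genes on the ozone libraries alone and of reads lost from Cvi-0 alleles were chosen after the results were seen, and the test by thinning was added after the data were seen. The margin of 1 jackknife SE for the odd library and for the Col-S baseline, and the reading of the splits of 12 libraries, were also set after their values were seen. The ozone response differed between genotypes in each of the 3 pairs by a test of the difference itself. edgeR called 673 genes for Col-S and Col-0, 4403 for Cvi-0 and Col-0 and 1003 for Col-S and Cvi-0, and camera called 11, 9 and 7 lists, of which 0 held with an estimated correlation. The 673 ranged from 304 to 1308 over the libraries left out.

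Other splits of the libraries exchanged genotype labels within treatments, with only the groups compared in the fit and no replicate block. For Col-S and Col-0, 6 of 100 splits gave at least the real 279 genes, the highest other being 732. For Cvi-0 and Col-0, 4 of 100 reached the real 4184, with 9101 as the highest other, and for Col-S and Cvi-0, 3 of 100 reached 1043, with 7130 as the highest other. Splits that mixed the genotypes in the ozone libraries gave at most 1, 215 and 218 genes. The 10 that did not, with the real one among them, gave at least 38, 2698 and 227. Genotype differences enter the spread of the mixed splits and set these counts apart, so the splits leave chance open for the 3 real counts. By share, the rule first set, 6 of 100 would not exclude it for Col-S and Col-0. The highest others exchanged all 3 ozone libraries, which tests the genotype difference. The splits also parted libraries of the same number, with which, as a hint, 18 of 18 libraries correlated best. With the replicate block the 673 genes were 1482.

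For comparisons of 3 libraries against 3 there are 10 splits, which are too few for a share under 0.05. Only the real split, 1 of 10, gave as many genes in each. The real counts were 10655 for ozone in Col-0, 14199 in Cvi-0 and 13048 in Col-S, and for the controls 4560 for Cvi-0 and Col-0, 105 for Col-S and Col-0 and 4653 for Col-S and Cvi-0. The highest other split gave 0 in each.

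The log2 response to ozone was 1.35 times as large in Col-S as in Col-0. With all libraries thinned to the smallest total it was 1.328 (1.32 to 1.34 over 5 further draws), which argues against unequal depth. The effect of 1 odd library stays open, because the ratio of 1.2177 without Col-0 control replicate 2 lies within 1 jackknife SE, 0.141, of the bound of 1.2 set for that test. Stress already present in the Col-0 controls stays open too, since with the Col-S controls as the baseline of both genotypes the ratio was 1.2089. Uneven exposure of the genotypes to ozone, and the genotype itself, were not tested and remain open.

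Salicylic acid genes had a median response difference of 2.29 between Col-S and Col-0. Raised levels in the Col-0 controls as the whole cause are argued against by the ozone libraries alone, where the median was 0.983 higher in Col-S (0.945 to 1.345 over the libraries left out). An odd Col-0 control as the whole cause is argued against by 1.55, the lowest median over leaving out each Col-0 control, which came without replicate 2 (2.476 was the highest). The drop from 2.29 to 1.55 came from leaving out that library. How much of the 1.55 rests on the levels of the other Col-0 controls stays open. Uneven exposure and the genotype itself were not tested for these genes and remain open.

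The Cvi-like genes on chromosomes 2 and 3 of Col-S could reflect Cvi-0 reads lost in alignment to the Col-0 reference. Of the 103 in the stretches, 42.7% were higher in Cvi-0 (exact 95% interval 33.02% to 52.85%), which lost reads cannot produce, and this argues against lost reads for all of them. For the 59 that were lower in Cvi-0, lost reads and lower expression cannot be told apart with 1 reference genome. Descent of both stretches from Cvi-0 would give such genes in either case, and the near-isogenic design names it.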

How the results depend on the processing

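Thinning was chosen after the data had been seen, and the other alternatives before. No gene called as reported and under an alternative changed direction. Which direction held more calls turned under some alternatives for ozone in Cvi-0 and Col-S, for the responses of Cvi-0 against Col-0 and Col-S against Cvi-0, and for the controls of Cvi-0 against Col-0 and Col-S. The counts of genes called for ozone in Col-0, Cvi-0 and Col-S, for Cvi-0 against Col-0 in response and in controls, and for Col-S against Cvi-0 in controls stayed within 1.5 times under every alternative. Over the libraries left out these counts ranged from 10396 to 11914, 13701 to 14682, 13136 to 14207, 3525 to 4622, 3906 to 5321 and 3407 to 4625.

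The 673 genes with a different response in Col-S and Col-0 were 1482 with the replicate block (1058 higher, 424 lower), 279 with only the groups compared in the fit (263, 16) and 1286 with the DESeq2 Wald test (1128, 158). They ranged from 304 to 1308 over the libraries left out. The 1003 for Col-S and Cvi-0 were 1522 with the block (879, 643), and 721 to 1143 over the libraries left out. The 174 between Col-S and Col-0 controls were 105 with only the groups compared (34, 71) and 285 with DESeq2 (96, 189), and ranged from 98 without Col-S control replicate 1 to 189 without Col-S ozone replicate 2. The fit with only the groups compared has fewer libraries to estimate the spread. For the other changes the cause was not tested.

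Of 189 list tests, 84 were called, 87 with the block, 79 with fry, 78 to 87 over the libraries left out and 0 with an estimated correlation, where the smallest adjusted p was 0.187. Under fry 24 calls were lost and 19 gained, and without Col-0 control replicate 2, 7 were lost and 6 gained. Among values of named genes under all alternatives, those no longer called were 9 of 2323 for ozone in Col-0, 16 of 2299 in Cvi-0, 4 of 2348 in Col-S, 219 of 1348 for Col-S against Col-0 in response, 58 of 2222 for Cvi-0 against Col-0 and 86 of 1173 for Col-S against Cvi-0. In the controls they were 114 of 2070 for Cvi-0 and Col-0, 31 of 375 for Col-S and Col-0 and 77 of 1793 for Col-S and Cvi-0.

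The response ratios ranged over the libraries left out from 1.22 to 1.40 for Col-S over Col-0, from 1.29 to 1.49 for Cvi-0 over Col-0 and from 0.933 to 0.991 for Col-S over Cvi-0. The 7 bins were 5 with a larger change, 5 with bins of 2 Mb, 7 with more genes per bin and 7 to 8 over the libraries left out. Although the reported fit took no replicate numbers as paired, 18 of 18 libraries correlated best with those of their own number. Thinning gave 11473, 14208 and 13768 calls for ozone and 590 for the response of Col-S against Col-0. In simulated data, 47 of 100 genes with a 2-fold and 88 with a 4-fold difference in response between Col-S and Col-0 were recovered.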

Other observations

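In controls, 22 genes of Col-S lay outside the range of both parents, 9 above and 13 below. The test of their position was chosen after the result was seen. AT3G47680 was at -9.88 on the log2 scale against Col-0 and -7.04 against Cvi-0, with 1 count in the Col-S controls. QQS was at -2.48 and -3.68, CNGC12 at -1.79 and -1.03, PAL4 at 1.29 and 1.42, and FMO-GS-OX2 at 1.02 and 1.85. These genes were chosen after their values were seen. Of the 22, 5 lay in the stretches on chromosomes 2 and 3. All 22 are among the 174 control calls of Col-S and Col-0, of which 110 lay there, so for the 5 position in a Cvi-like stretch stays open. The others lay outside, which argues against it for them, though 1 Mb bins leave edges uncertain. New combinations of Col-0 and Cvi-0 alleles were not tested.

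Outside the comparisons, Col-0 control replicate 2 had PR5 at 86.6 CPM against 17.7 and 26.8 in the other Col-0 controls, and HR4 at 181 CPM against 33.5 and 49.4.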
